A study of Mus musculus with 4 samples.

How the data were processed

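Leukocytes were washed from the peritoneal cavity of female C57BL/6 mice and sorted for CD45, the pan-leukocyte marker. Per the series' design text, the washes of 3 mice were pooled in each of 2 conditions: mice injected with buffer (naive) and mice injected 18 hours earlier with the parasite Trypanosoma brucei brucei (infected). Per the labels, each pool gave a cDNA library made by droplet-based 3' sequencing and a library of antibody-derived tags (ADT) from the same cells, so the 4 GEO samples hold 1 biological sample per condition.

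Per the submitters' processing notes, the authors used Cell Ranger and the mouse build GRCm38. The program's version and the annotation release are not given in the sources used here. The deposited matrices hold raw UMI counts per feature and barcode, unfiltered, for 55385 genes and 168 antibodies. Per the file headers, 4 deposited tables list the cells the authors kept, each with its condition and, in the authors' own terms, a doublet score and the percent of mitochondrial UMIs. The table of all cells names 19 classes. The other 3 give cluster numbers for large peritoneal macrophages (LPM) of the naive library, the infected library and both jointly. The table of the infected library lacks all 96 infected cells of joint cluster 4, and no reason is given. The authors' filters on cells, clustering settings and doublet caller are not given in the sources used here. The deposited percent of mitochondrial UMIs had a median of 3.09 in naive and 1.82 in infected cells, above the 2.26 and 1.43 recomputed from the deposited counts, so filters used the recomputed percent.

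Cells and classes were taken from the authors' annotation, 1057 naive and 3025 infected cells. No cells were removed as doublets in the main values. The authors' deposited doublet score exceeded 0.5 in 272 naive cells (25.7%) and 279 infected cells (9.22%), and leaving these out was an alternative. UMI counts were summed over the cells of a class in each library and expressed as CPM of the class total. Shares carry exact Clopper-Pearson intervals, summed counts exact Poisson intervals and CPM ratios exact conditional binomial intervals, all at 95%. They cover counting error only, save for class II genes within clusters, where cells were drawn anew. A count of 0 was set to a floor of 3 counts over the class for a ratio, which is then a bound.

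No test was made and no p-value is given, since cells are not replicates. A gene was called higher or lower by size: at least 50 UMIs over both libraries in the class, at least 50 CPM in 1 of them, and the bound of the ratio's interval nearest 1 at least 1.5-fold away from it. Classes with at least 50 cells in each library were compared. Monocytes, NK cells and mast cells, with at least 30, were added after seeing the data. No class had more marker genes of another class than of its own among its top 10 genes. Naive B cells had 0 of either kind and infected B cells 1 of their own, so the check says little of B cells. The genes named were fixed by rule before the data were examined: for LPM the 12 largest and 12 smallest ratios past the size rule (5 and 5 for other classes and for LPM clusters), leaving out predicted, mitochondrial, ribosomal protein, haemoglobin, histone and antigen receptor segment genes and Malat1. To these were added Vsig4, Timd4, Gata6, Icam2, Adgre1, Cd5l, C3, Itgam, Cxcl13, Selp, Marco and Lyve1 whatever their value, and up to 4 members of each gene list. The comparison of the libraries within LPM clusters was not in the plan. Its further genes, such as Arg1 and Lcn2, were among those called in all LPM, so they are no independent result. For each of 29 gene lists fixed in advance, the median log2 ratio was set among 10000 random lists of the same size matched on expression decile, as a description of these libraries. Markers of classes, the size rule and the lists were likewise written before the data were examined. Positions come from a RefSeq table of GRCm38.p6, which held all 192 named genes.

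Shares of cells with a Vsig4 UMI were computed at full depth and after thinning each cell to 1000 UMIs. LPM with and without Vsig4 were compared after thinning to 7824 UMIs, the 10th percentile of the shallower library. The plan used the VSIG4 antibody for this split where the panel held it. The panel held 18 of the 20 antibodies fixed in advance, without VSIG4 or CD40, and the infected matrix held 0 antibody counts against 1507332 in naive. So the split used Vsig4 UMIs, and the planned comparison of surface protein between conditions was replaced by a description of the naive library.

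The size rule was tested on simulated Poisson counts drawn from the real class means and totals. All 55385 genes were run, with 50 genes per fold size altered. Such counts follow the error model of the intervals and carry no spread between cells. Coverage and false calls were thus set by that model, and say nothing of genes whose UMIs come from few cells. For LPM it recovered 98% of 2-fold, 90% of 0.5-fold, 100% of 4-fold and 98% of 0.25-fold genes, with 0 in the wrong direction, 0 unaltered genes called and 95.5% of intervals holding the true ratio. For B cells the same order gave 100%, 92%, 100% and 100%. Shallow classes were weaker for small folds: neutrophils gave 30%, 26%, 98% and 82%, and NK cells 26%, 30%, 100% and 40%.

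Alternatives fixed in advance covered cells (raw barcodes with at least 500 UMIs and under 10% mitochondrial UMIs, marker-based classes, minimum UMIs), scaling (TMM from edgeR, the median of gene ratios, totals without mitochondrial and ribosomal protein genes), filters on low counts, the fold bound, per-cell means, thinning, subtraction of free RNA estimated from barcodes with 1 to 50 UMIs, own Leiden clusters at resolution 0.5, and LPM split into upper and lower parts by Vsig4 CPM. After seeing the data, a doublet score of at most 0.5, a full droplet load of free RNA taken from unannotated barcodes with 100 to 299 UMIs, leaving out clusters, leaving out each gene's top cell, clusters of LPM without SPM, and shares without monocytes and neutrophils were added, with cells drawn anew for class II genes within clusters. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors alone. Deposited plot coordinates were not used here. Barcodes outside the authors' annotation were used for the free RNA profile, for the alternative on raw barcodes and for the count in the closing section.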

Results

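Leukocytes of the peritoneal cavity were profiled by CITE-seq, which reads the transcripts of single cells and, through tagged antibodies, their surface proteins. The design sets mice 18 hours after infection with Trypanosoma brucei brucei, an extracellular protozoan parasite, against buffer-injected mice. Each condition is 1 library from the pooled washes of 3 mice. The series title names macrophages with VSIG4, a complement receptor, so the comparisons ask how resident macrophages, their Vsig4 and the other leukocytes differed between the libraries. The naive library held 24835279 gene UMIs and the infected library 68527928. Of these, 9877817 (39.8%) and 42135228 (61.5%) lay in the 1057 naive and 3025 infected cells of the authors' annotation. The median cell held 8199 UMIs and 2959 genes in naive, and 13171 UMIs and 3805 genes in infected. There were no replicates, so no difference could be set against a spread between samples, and all intervals are 95% intervals of counting error, except where cells were drawn anew.

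Monocytes and neutrophils, phagocytes that circulate in blood, took larger shares of the infected library, and B cells, T cells and mast cells smaller ones. Monocytes were 3.60% of naive cells (38 of 1057, exact Clopper-Pearson interval 2.56 to 4.90%) and 24.5% of infected cells (740 of 3025, 22.9 to 26.0%), a ratio of 6.80 (4.91 to 9.69). Neutrophils were 7.0% (5.54 to 8.71%) and 21.4% (20 to 22.9%), a ratio of 3.06 (2.40 to 3.95). B cells were 30.5% and 18.0%, a 1.69-fold lower share (1.47 to 1.94), and T cells were 30.5% and 13.1%, a 2.33-fold lower share (2.01 to 2.71). Mast cells, the granulated source of histamine, were 4.35% (46 cells) and 1.12% (34 cells), a 3.87-fold lower share (2.43 to 6.22), at a median depth of only 545.5 and 706.5 UMIs.

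LPM, the resident macrophages of the cavity, were 16.2% of naive (171 cells, 14.0 to 18.5%) and 13.7% of infected cells (413 cells, 12.4 to 14.9%), a ratio of 0.844 whose interval (0.704 to 1.01) included 1. So did those of small peritoneal macrophages (SPM, ratio 0.882), NK cells (0.864) and dendritic cells (1.41). Fibroblasts were 0 of 1057 naive cells, which allows a share of up to 0.284% (3 cells; exact upper bound 0.348%), and 1 of 3025 infected cells. All shares are of CD45-sorted cells kept by the authors, so they give proportions and not numbers per mouse. Classes drawn from marker scores moved the monocyte ratio to 10.4, and raw barcodes with at least 500 UMIs and under 10% mitochondrial UMIs moved the neutrophil ratio to 2.03. Shares also depend on each other: without monocytes and neutrophils, B cells were 34.1% of 945 naive and 33.4% of 1637 infected cells (ratio 0.979, 0.851 to 1.13), T cells had a ratio of 0.708, and LPM were 18.1% and 25.2% (1.39, 1.16 to 1.68).

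**Figure D1:**
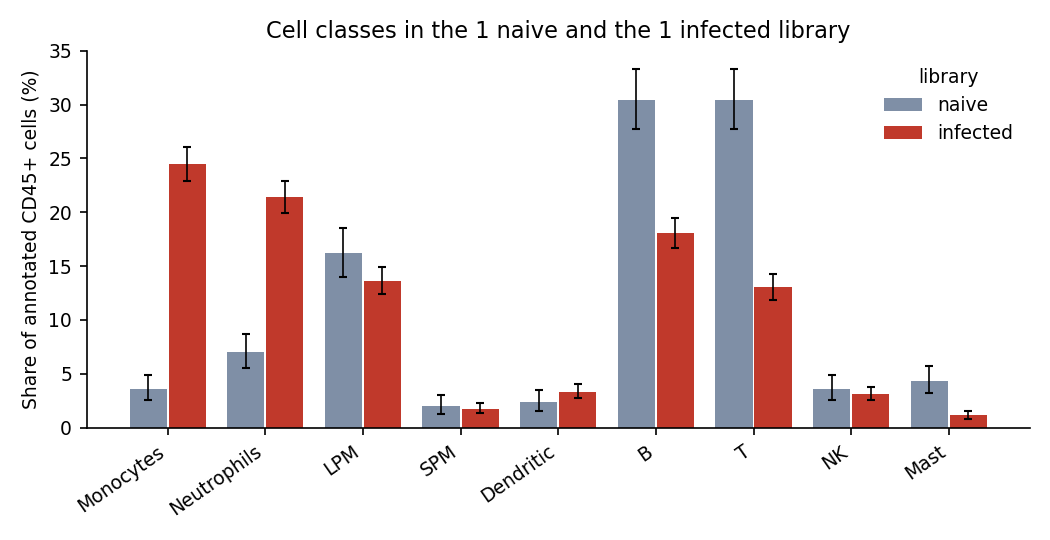
Share of annotated CD45+ cells (%, vertical axis) in each class for the naive (grey) and the infected (red) library, with exact 95% binomial intervals as error bars. Monocytes stand at 3.60% and 24.5% and neutrophils at 7.0% and 21.4%, while B and T cells both start from 30.5% in the naive library.

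In LPM, many transcripts of the interferon response and that of arginase were higher in the infected library, and some of MHC class II and cell division were lower. Arg1, the enzyme that breaks down arginine (chromosome 10, 24915207 to 24927470 of GRCm38), stood at 1539.6 CPM in infected and 256 CPM in naive LPM, a ratio of 6.02 (5.57 to 6.51). Oasl1, Rsad2, Ifit1 and Isg15, antiviral effectors induced by interferon, were 7.81-, 7.07-, 6.35- and 5.47-fold higher. Lcn2, the iron-withholding lipocalin 2, was 9.94-fold higher (7.58 to 13.3). Mki67 and Top2a, genes of dividing cells, were 7.08- and 3.67-fold lower, though at equal depth their shares of positive LPM had overlapping intervals. The class II chains H2-Eb1, H2-Aa and H2-Ab1 with their invariant chain Cd74 were 4.73-, 4.04-, 3.08- and 3.51-fold lower.

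By the rule of size, not a test, 126 of 3755 LPM genes deep enough to be called were higher and 88 were lower. Scaling by TMM shifted every log2 ratio by 0.10 and gave 194 higher and 55 lower, with all 126 among the higher and 55 of the 88 still lower. Spp1, which encodes the secreted protein osteopontin, had a ratio of 8.86 (5.32 to 16), from 41 of 413 infected and 2 of 171 naive LPM. Tgm2, a protein-crosslinking transglutaminase, was 5.79-fold higher, the surface protein gene Ly6a 3.94-fold, Usp18, which removes ISG15 from proteins, 3.91-fold, the interferon-induced GTPase gene Gbp5 3.84-fold and Marcksl1 3.77-fold. Among the smallest ratios were also Stmn1, a microtubule regulator (6.60-fold lower), Ypel2 (3.19-fold), the kinase gene Rps6ka5 (2.95-fold), Arhgap6 (2.74-fold), the laminin gene Lama3 (2.72-fold) and Ldlrad3 (2.58-fold).

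Most genes that mark LPM did not pass the size rule. Gata6, the transcription factor of the LPM programme, had a ratio of 0.844 (0.766 to 0.931). Timd4, a receptor for apoptotic cells, had 0.940, Icam2 1.06, Adgre1, which encodes F4/80, 1.13, and Selp 0.999. Itgam, the complement receptor chain CD11b, had 1.19, Cd5l 1.24, Lyve1 1.13 (0.735 to 1.79) and C3, the central complement component, 0.619, and none of these passed the size rule. Of the genes fixed in advance, the scavenger receptor gene Marco (2.41) and Cxcl13, a chemokine for B cells (2.08), were higher.

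**Figure D2:**
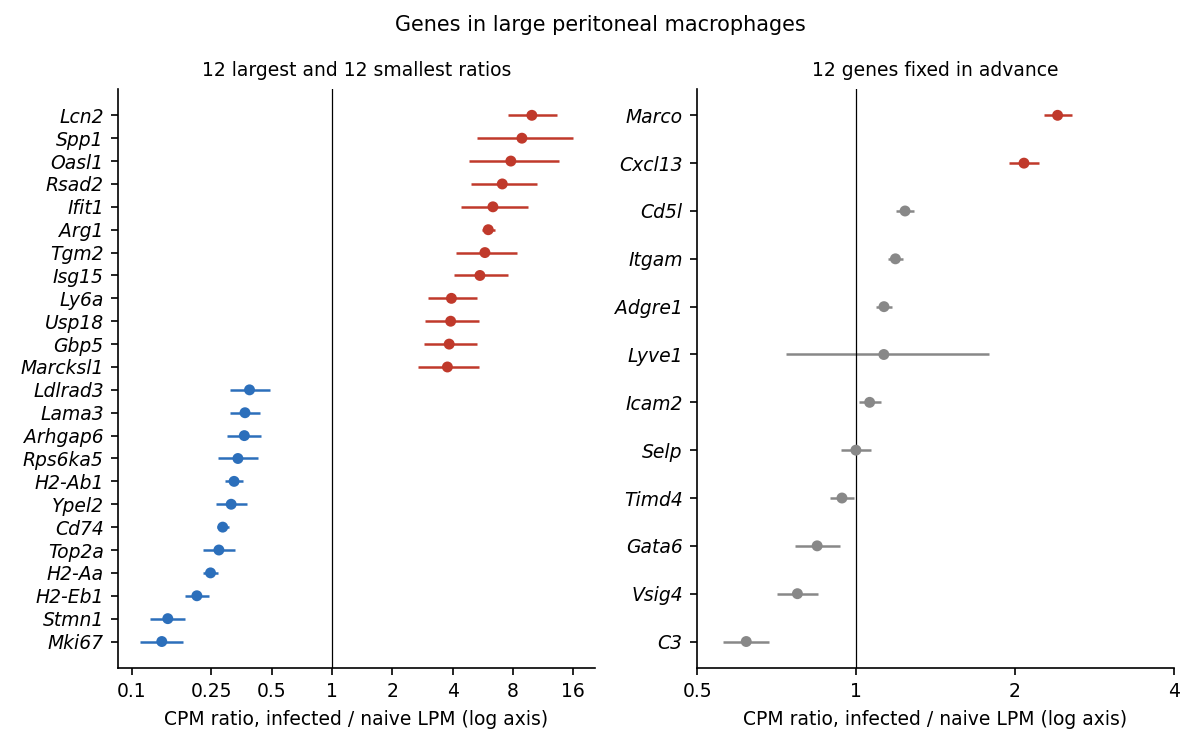
CPM ratio of infected to naive LPM (log axis) with the 95% interval of counting error for the 12 largest and 12 smallest ratios and for 12 genes fixed in advance, with red for higher, blue for lower and grey for neither by the rule of size. Lcn2 stands highest at 9.94, while Timd4, Icam2 and Selp lie between 0.940 and 1.06.

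The type I interferon list had 24 of 36 members higher in LPM and a median log2 ratio of 1.47, above all 10000 random lists. The interferon-gamma list had 7 of 30 higher with a median of 0.89, among them the GTPase genes Gbp2 (3.11-fold), Irgm1 (2.46-fold) and Iigp1 (2.04-fold). Of inflammatory cytokines and chemokines, 4 of 25 were higher (median 1.40, with the 6 members at 0 UMIs in 1 library set at the floor): Lcn2, the chemokine genes Ccl6 (2.97-fold) and Ccl9 (1.71-fold), and Saa3, an acute-phase protein gene at 28989 CPM in infected LPM (2.30-fold). NF-kappaB targets had 2 of 20 higher (median 0.55), the prostaglandin synthase gene Ptges (2.22-fold) and the mitochondrial dismutase gene Sod2 (2.12-fold). The list of neutrophil granule and activation genes had 2 of 19 higher (median 0.66). Neutrophil markers had a median of 0.43 with none called, and of -0.29 once the profile of nearly empty barcodes was subtracted. The free RNA share so estimated was 0.90% in naive and 3.14% in infected LPM. The medians of these gene lists, markers aside, also lay above all 10000 random lists.

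In the metabolic lists, glycolysis and hypoxia had 5 of 20 higher (median 0.43), including Acod1, the itaconate-producing enzyme (3.60-fold), the lactate exporter gene Slc16a3 (2.03-fold) and Pgk1 (1.90-fold). Oxidative phosphorylation had 2 of 25 higher (0.37), among them cytochrome c, Cycs (1.91-fold). The oxidative stress list had 1 of 19 higher (0.37) and the unfolded protein response 1 of 16 (0.34), the secreted stress protein gene Manf (1.78-fold). MHC class I presentation had 2 of 18 higher (0.39), the proteasome activator gene Psme2 (1.99-fold) and the class I transactivator gene Nlrc5 (1.90-fold).

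The cell cycle list had 4 of 23 members lower and a median of -1.71, below all random lists, and the MHC class II list had 5 of 13 lower and a median of -0.81. Complement had 2 of 19 lower (median -0.33), among them the component gene C4b (1.64-fold). Cholesterol and lipid handling had 1 higher and 3 lower of 21 (-0.13): the lipid droplet coat gene Plin2 was 1.83-fold higher, and the apolipoprotein genes Apoc1 and Apoe and the fatty acid carrier gene Fabp4 were 2.57-, 1.59- and 1.88-fold lower. The anti-inflammatory and wound-healing list was mixed (median 0.17), with Arg1 and Retnla (2.36-fold) higher and the phosphatase gene Dusp1 and the lipid receptor gene Trem2 2.46- and 2.10-fold lower. Retnla turned lower, with a log2 ratio of -0.98, in the deposited LPM subset, which adds SPM.

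The remaining lists had at most 2 members called in either direction in LPM. The LPM identity list had a median of -0.05 (2 of 24 higher, 1 lower), scavenger receptors 0.21 (2 of 22 higher), pattern recognition receptors 0.02 (2 of 22 higher, among them the RNA sensor gene Ddx58 at 2.87-fold), immediate early and dissociation stress genes 0.30 (1 of 20 higher, 1 lower) and lysosomal genes 0.03 (1 of 22 lower). No member was called among genes of coagulation and adhesion (median 0.08), B cell activation (0.33) and NK and T cell activation (-0.27). None was called either among markers of B cells (-0.06), T cells (-1.40), mast cells (-0.10), erythroid cells (-2.14), mesothelial cells (-1.27) and neutrophils (0.43).

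The deposited joint clustering splits LPM and a few SPM into 5 clusters, of which 2, 3 and 4 took different shares of the libraries. Cluster 2 held 49.5% of the 184 naive cells (42.0 to 56.9%) and 7.84% of the 421 infected cells (5.46 to 10.8%), clusters 0, 1 and 3 held 24.5%, 19% and 7.07% of the naive cells, and clusters 0, 1, 3 and 4 held 22.8%, 22.1%, 24.5% and 22.8% of the infected cells. Cluster 4 held 0 of 184 naive cells, which allows a share of up to 1.63% (3 cells; exact upper bound 1.98%). A cluster mostly of 1 library may be that library and not a type of cell. Leaving out cluster 4 gave 82 LPM genes higher and 62 lower, of which 80 and 61 were among the 126 and 88, with Arg1 at a log2 ratio of 2.09. Leaving out cluster 2 gave 94 higher and 56 lower, of which 81 and 39 were among them, and ended the class II calls, with H2-Aa at a log2 ratio of -0.42 and Cd74 at -0.33.

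The clusters are described by their leading genes. In naive cluster 0 the cell division genes Pclaf, Cenpf and Mki67 led, with Mki67 at 220.0 CPM against 3.03 CPM in the other naive cells, and in infected cluster 0 the replication genes Uhrf1 (24.1-fold), Top2a (14.0-fold) and Mcm7 (11.4-fold) led. Cluster 2 held 12 SPM among its 91 naive and 7 among its 33 infected cells. H2-Aa stood there at 1142 CPM against 135 CPM in other naive cells, and at 847 CPM in its naive LPM alone, with UMIs in 78.5% of them. In infected cells of the cluster H2-Eb1 was 10.8-fold above the others, but its 7 SPM held 94.4% of these UMIs, and H2-Aa stood at only 78.7 CPM in its 26 infected LPM, with UMIs in 26.9% of them. Retnla led in naive cluster 2 (45.0-fold, 55.6% of its UMIs from 1 cell), with 524 UMIs in SPM and 43 in LPM. Infected cluster 4 was led by AA467197 (40.8-fold), the chemokine genes Ccl7 (27.7-fold) and Cxcl10 (25.5-fold), and Stfa3 (27.4-fold). The small naive cluster 3 (13 cells) was led by Emp1 and Cxcl13 (3.75-fold), each with over 50% of UMIs from 1 cell, and infected cluster 3 by S100a9, with 93.2% from 1 cell. Naive cluster 1 was led by Saa1, with 70.3% from 1 cell, and infected cluster 1 by Nr3c2, the mineralocorticoid receptor gene (2.89-fold).

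Within the 4 clusters with cells of both libraries, the interferon list had medians of 1.27, 1.05, 0.78 (0.54 in LPM alone) and 1.17 log2 in clusters 0 to 3, each above all random lists. It had 14, 13, 3 (1 in LPM alone) and 16 members called higher, and in cluster 2 Isg15 had a ratio of 0.880 (0.315 to 2.17). Arg1 differed by cluster: its ratio was 4.34 in cluster 0, 1.22 (1.06 to 1.40) in cluster 1, 2.42 in cluster 2 (1.96, 1.40 to 2.71, in its LPM alone) and 4.42 in cluster 3, and it reached 3505 CPM in infected cluster 4. Lcn2 had ratios of 5.82, 39.0 (13.2 to 189.7, on 3 naive UMIs), 7.01 (8.33 in LPM alone) and 7.62. Mki67 was 10.7-fold lower within cluster 0, at 20.5 against 220.0 CPM, with its naive UMIs in 22 of 45 cells. Marco was 2.60- and 3.59-fold higher in clusters 0 and 1, and in cluster 2 had a ratio of 1.34, or 2.23 in LPM alone. In cluster 3 its ratio was 0.735, with 56.4% of the naive UMIs from 1 of 13 cells, and 1.53 (1.30 to 1.81) without that cell. The 5 class II genes called lower in LPM had a median log2 ratio of -3.04 among LPM of cluster 2 (-4.94 to -1.95, with cells drawn anew 10000 times), and of -0.82, -1.19 and -0.52 in clusters 0, 1 and 3, where such intervals included 0. By the size rule, which covers counting error only, H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were lower in cluster 1 (2.20-, 2.29-, 2.64- and 2.59-fold). Cd74 was also called lower in cluster 3, SPM included.

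**Figure D3:**
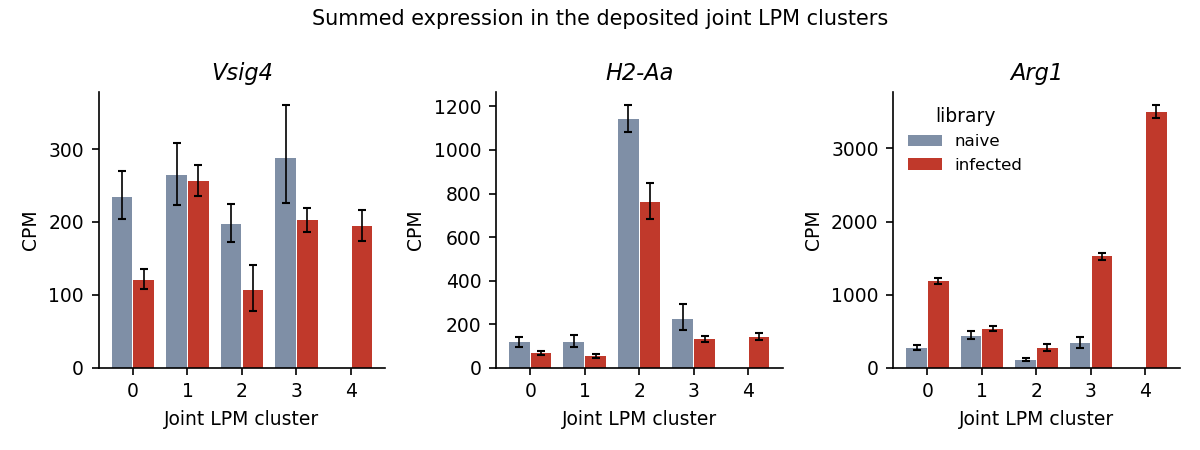
CPM of Vsig4, H2-Aa and Arg1 (vertical axes) summed over each deposited joint LPM cluster (horizontal axis) in the naive (grey) and infected (red) library, with exact 95% Poisson intervals. H2-Aa peaks in cluster 2 at 1142 CPM in naive, and Arg1 peaks in cluster 4, which has infected cells alone, at 3505 CPM.

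Vsig4, the gene of the series title (chromosome X, 96247201 to 96293438 of GRCm38), was found in a part of LPM in both libraries. Its summed level was somewhat lower in the infected library. At least 1 UMI was present in 36.8% of naive LPM (63 of 171, 29.6 to 44.5%) and 29.8% of infected LPM (123 of 413, 25.4 to 34.4%), at median depths of 15401 and 23549 UMIs. In B cells, which should lack the gene, the shares were 1.25% and 2.73% at median depths of 11381 and 14797.5 UMIs. Thinned to 1000 UMIs per cell, with 0 LPM left out in either library, the shares were 14.6% (9.69 to 20.8%) and 12.3% (9.33 to 15.9%), against 0 of 319 naive B cells (exact upper bound 1.15%) and 0.391% of infected B cells. Summed expression was 246 CPM (227 to 266) and 190.3 CPM (182 to 199), a ratio of 0.774 (0.707 to 0.848) that did not pass the size rule. This interval covers counting error only, and those of the shares of positive LPM overlapped between the libraries.

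Vsig4 was unevenly spread over LPM. Positive cells carried 10.3 UMIs on average in naive and 14.8 in infected, up to 46 and 55 in 1 cell, and at least 2 UMIs were present in 28.7% and 24.9% of LPM. The same UMIs spread evenly by depth would have left 94.9% and 95.5% of LPM positive. SPM held 27.2 CPM in naive (9 UMIs) and 3.31 CPM in infected (4 UMIs), and monocytes 0 UMIs in 38 naive cells (exact upper bound 9.25% of cells with a UMI at this depth) and 2.0 CPM in infected cells. By cluster, Vsig4 ranged from 198 to 287 CPM in naive and from 106 in cluster 2 to 257 in cluster 1 in infected cells. Within cluster 0 it was 1.94-fold lower in infected. In clusters 1, 2 and 3 its ratios were 0.973 (0.812 to 1.17), 0.537 and 0.704, and none was called. In LPM alone, infected cluster 2 stood at 157 CPM. The 2.42-fold range among infected clusters was 1.10-fold among own Leiden clusters.

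The split of LPM by Vsig4 asks which other genes go with it. In naive LPM thinned to 7824 UMIs (154 of 171 kept), 47 cells with Vsig4 had 6 genes higher and 2 lower than 107 cells without. Higher were the apolipoprotein gene Apoc1 (2.57-fold), Hpse, which encodes heparanase (2.39-fold), Ofcc1 (2.32-fold), Cxcl13 (2.16-fold), the ligand gene Wnt2 (1.98-fold) and Pf4, platelet factor 4 (1.72-fold). For Cxcl13, 1 cell gave 33.6% of the UMIs of the naive cells with Vsig4. Lower were H2-Eb1 (2.24-fold) and the protease inhibitor gene Slpi (1.90-fold). In infected LPM (396 of 413 kept), 100 cells with Vsig4 had 3 genes higher and 3 lower than 296 without. Cxcl13 was again higher (1.73-fold), and Slpi (1.77-fold), Cd74 (2.14-fold) and Saa1 (2.42-fold) were lower. The other 2 higher genes, S100a9 and S100a8, took 97.2% and 86.0% of their UMIs from 1 cell. In the split into upper and lower parts by Vsig4 CPM, Cxcl13 was called in neither library. Of the other genes above, only Apoc1, Ofcc1, Pf4 and Slpi were called again in naive, and only Cd74, S100a8 and S100a9 in infected.

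Most identity genes were not called across this split: Gata6 had ratios of 0.914 in naive and 0.95 in infected, Adgre1 1.01 and 1.10, Icam2 1.01 and 1.04, and Timd4 1.37 (1.19 to 1.58) and 1.07. Of the LPM identity list, 2 of 23 members were higher in naive, Cxcl13 and Apoc1, and 1 in infected, Cxcl13. Arg1 had 1.5 (1.17 to 1.91) in naive and 1.03 in infected, and Marco 1.31 and 1.59, below the size rule. The type I interferon list had medians of 0.19 and 0.03 log2 across the split, and the cell cycle list -0.26 and -0.31, below nearly all random lists (percentiles 0.84 and 0.02).

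Surface protein was read in the naive library alone, where 164 antibodies were detected and the median cell held 222 ADT counts. Tim4, the product of Timd4, gave 71.1 counts per LPM against 0.875 per other cell (865 cells without SPM), and as a share of all ADT counts it was 33.0-fold higher (30.7 to 35.6). CD105, a TGF-beta co-receptor, was 64.8-fold higher, F4/80 24.6-fold, CD169, a sialic acid-binding receptor, 16.9-fold, the integrin chain CD49f 16.7-fold and CD14, the LPS co-receptor, 13.3-fold. In other cells CD105, F4/80 and CD169 averaged at most 0.128 counts, below the highest isotype control there (0.666), so these folds are set against background. CD11b was 8.49-fold, CD102 7.58-fold, the co-stimulatory CD86 4.77-fold, the CSF1 receptor CD115 4.74-fold and CD80 2.41-fold higher, and CD54 1.21-fold, at 29.6 counts per LPM against 9.91 per other cell. The T cell proteins CD4, CD90_2 and CD5 were 43.3-, 33.5- and 27.2-fold lower, the mast cell receptor CD117 28.7-fold and the adhesion protein CD31 27.9-fold, each at a mean of at most 1.11 counts per LPM. These means lay below the highest isotype control in LPM, so these folds too are set against background.

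MHC class II protein (IA_IE) was 5.16-fold lower in naive LPM than in other cells, CD11a 19.7-fold, Ly6C 14.0-fold and PD-L1 (CD274) 2.13-fold, all as shares of ADT counts. Ly6G lay below the highest isotype control in both groups. Per cell, IA_IE gave 5.65 counts in LPM against 11.8 in other cells, and CD274 was not lower, at 4.27 against 3.70. The highest isotype control gave 1.92 counts per LPM and the next 0.444. The means of CD64 (0.462), CD16_CD32 (0.497), CD163 (0.316), CD206 (0 counts), CD11a, Ly6C and Ly6G lay below the highest, so they were not separated from background there by their means. Of 190 CD163 counts in the LPM clusters, 187 lay in cluster 2, at 2.05 per cell with its 12 SPM included. The mean of 0.316 in LPM alone leaves most of these counts to SPM, so no group of LPM with CD163 is shown. Within naive LPM, class II protein followed the RNA: the 79 LPM of cluster 2 gave 9.05 counts per cell against 2.73 in the 92 of other clusters, a 4.57-fold higher share (3.95 to 5.29). Tim4 (1.04) and CD11b (1.05) had ratios of shares near 1. Per cell both were lower in cluster 2, Tim4 at 60.7 against 80.1 counts and CD11b at 48.9 against 64.0.

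The other classes were compared to ask how far the difference reached beyond macrophages, and interferon-stimulated genes led in most of them. In B cells, Rtp4 and Ifit3 were 7.36- and 7.11-fold higher, and in CD4 T cells Isg15 was 8.44-fold higher. Ifit1 was 14.0-fold higher in naive CD8 T cells (4.61 to 69.3, on 3 naive UMIs), and Ifit2 75.6-fold in neutrophils (13.5 to 2989, on 1 naive UMI). The type I interferon list had 14 of 36 members higher in B cells (median 1.65), 16 in CD4 T cells (1.36), 3 in naive CD4 T cells (1.20), 7 in naive CD8 T cells (1.17) and 22 in neutrophils (1.54). All these medians lay above all 10000 random lists. In the classes added after seeing the data, 15 were higher in monocytes (1.02), 2 in NK cells (0.31) and 0 of 24 measured in mast cells (0.39). Free RNA bears on some of these: the NK median was 0.0125 with a full droplet load taken off, and that of naive CD4 T cells 0.72 with the profile of nearly empty barcodes subtracted.

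**Figure D4:**
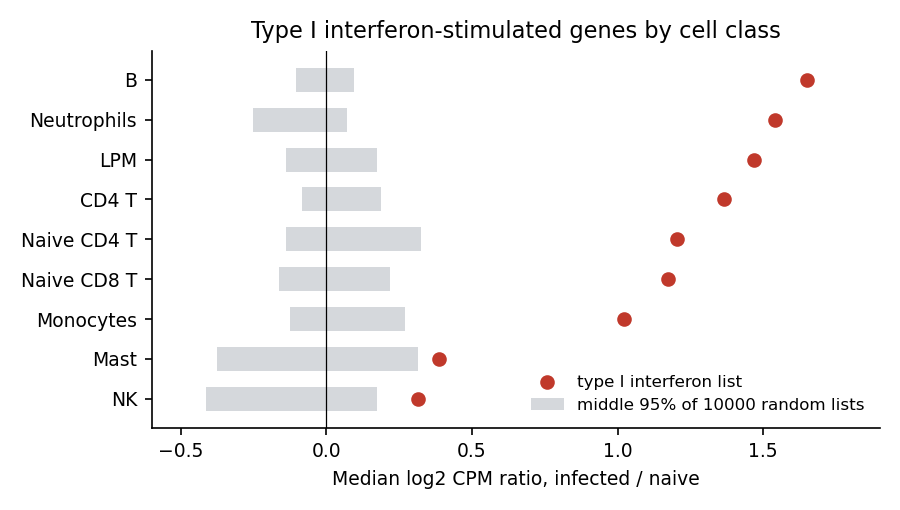
Median log2 CPM ratio of the type I interferon list in each class (red points, horizontal axis), with the middle 95% of 10000 expression-matched random lists in grey. Medians run from 0.31 in NK cells to 1.65 in B cells, and each lies to the right of its random range before any correction for free RNA.

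B cells had 46 genes higher and 15 lower by the rule of size. Transcripts of other cells moved with them: neutrophil markers had a median log2 ratio of 2.36, the neutrophil granule list 2.12, scavenger receptors 1.01 and LPM identity genes 0.49, each above all random lists. The share of free RNA estimated from nearly empty barcodes was 0.95% in naive and 9.63% in infected B cells, and subtracting it left an interferon median of 1.25. It gave 40 genes higher, 35 of them among the 46, and 42 lower, 11 of them among the 15. Ifi213 (3.83-fold) and Slfn1 (3.70-fold), both interferon-responsive, were higher, and S100a9 (34.7-fold) took 79.3% of its UMIs from 1 cell. Lower were the tumour suppressor gene Fhit (2.40-fold), Tppp3 (2.31-fold), Ifi27 (2.24-fold), the nuclease gene Dnase1l3 (2.11-fold) and Tenm4 (2.09-fold). Saa3 was 2.03-fold higher in B cells, 2.02-fold in CD4 T cells, 2.14-fold in naive CD4 T cells and 2.03-fold in neutrophils, at 196 to 830.4 CPM, near its 2.30-fold difference in LPM.

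CD4 T cells had 49 genes higher and 5 lower. Ifit3 (6.65-fold), Usp18 (5.79-fold), Ifit1 (5.62-fold) and Igkc (5.74-fold, 65.9% from 1 cell) were higher, and B cell markers moved with them, with 2 of 10 called higher and a median of 1.75. Lower were St3gal6 (2.08-fold), the cell cycle kinase gene Cdk6 (2.03-fold), the chemokine gene Ccl5 (1.88-fold), the survival gene Bcl2 (1.75-fold) and Cmss1 (1.74-fold). Naive CD4 T cells had 21 higher and 7 lower, with the nucleic acid sensor gene Zbp1 5.65-fold, Gbp2 3.99-fold, Iigp1 3.61-fold and Phlpp1 3.48-fold higher, and Ttc28 3.65-fold, Kcnq5 3.35-fold, Fhit 3.25-fold and Id2 2.70-fold lower. Pid1 there took 78.0% of its UMIs, and the lower S100a8 100%, from 1 cell. Leaving out each gene's top cell gave 4 lower, all among those 7.

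Naive CD8 T cells had 30 genes higher and 8 lower. Igfbp4 (6.18-fold), the IL-12 receptor chain gene Il12rb2 (5.43-fold), the kinase gene Mapkapk2 (5.19-fold) and Skap2 (4.97-fold) were higher. Lower were Nmt2 (2.78-fold), the granzyme gene Gzma (2.57-fold), the chemokine receptor gene Cx3cr1 (2.52-fold), Zeb2 (2.20-fold) and Cmss1 (1.87-fold), and from the list of NK and T cell activation Gzma and Ccl5 (1.59-fold) were the 2 members lower. The haemoglobin genes Hbb-bs and Hba-a1 took 100% of their naive UMIs from 1 cell.

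Neutrophils had 98 genes higher and 35 lower, on 74 naive cells. Cxcl10 (45.7-fold, 8.17 to 1809) and Ly6a (13.7-fold, 2.42 to 545.7) rested on 1 naive UMI each, Ifit3 and its near-identical copy Ifit3b were 12.8- and 11.8-fold higher, and Tnf, with 205 infected and 0 naive UMIs, was at least 6.34-fold higher. MHC class I presentation had 7 of 18 members higher (median 0.93), among them H2-Q6 (4.98-fold, in a family of similar genes) and the peptide transporter gene Tap2 (3.13-fold), and the interferon-gamma list had 8 of 29 higher (0.86). The immediate early genes Fos and Egr1 were 1.73- and 2.02-fold lower. Map4k5 (3.75-fold), Ranbp3 (3.68-fold), Cog5 (3.4-fold), the lipid transporter gene Abca3 (3.37-fold) and Ebf1 (3.73-fold, 83.8% from 1 cell) were also lower. T cell markers had a median of -2.43, below all random lists, and 1 of 10 B cell markers was lower. Leaving out each gene's top cell gave 21 lower, 18 of them among the 35, and scaling by the median gene ratio gave 137 higher, with all 98 among them, and 19 lower, all among the 35.

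Monocytes, with 740 infected and 38 naive cells, had 216 genes higher and 177 lower. Arg1 was 381-fold higher (105 to 3146, on 2 naive UMIs) at 1816 CPM, close to its level in infected LPM, the monocyte chemoattractant gene Ccl2 91.5-fold (31.3 to 443.9, on 3), and Spp1 37.3-fold (6.68 to 1475, on 1). Ccl7 and Ccl12, chemokines of the same family, were at least 42.2- and 39.0-fold higher. Glycolysis and hypoxia had 10 of 20 members higher (median 1.07), including Slc16a3 (6.84-fold) and Tpi1 (3.53-fold). MHC class II had 7 of 13 lower (-1.59), with H2-Ab1 3.91-fold lower, and the other smallest ratios were those of Hpgd, which degrades prostaglandins (86.5-fold lower), Clec4b1 (9.27-fold), Zbtb16 (6.69-fold), Tmem176a (6.63-fold) and Dpp4 (6.42-fold). The median doublet score was 0.497 in naive and 0.0704 in infected monocytes, and the B cell gene Ighm was 3.28-fold lower in infected.

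NK cells had 36 genes higher and 21 lower on 34 naive and 92 infected cells. T cell markers had a median of -1.69 and the cell cycle list -1.27, both below all random lists. From the list of NK and T cell activation, 5 of 20 members were higher (median 0.57), among them the granzyme gene Gzmb (2.54-fold, 1.91 to 3.43), the transcription factor gene Irf8 (2.83-fold) and the chemokine gene Ccl4 (2.53-fold). Gtf2h2 (13.6-fold, 2.32 to 546.6), the granzyme inhibitor gene Serpinb9b (11.5-fold, 3.08 to 96.4), Spp1 (6.49-fold) and Ppa1 (5.81-fold, 1.90 to 28.9) had the largest ratios, on 1, 2, 9 and 3 naive UMIs, with Gzmc taking 85.5% of its UMIs from 1 cell. Ly6c2, a surface marker gene, was 7.65-fold lower, and Cep83, Inpp4a, Tmem161b and Gmeb2 were 2.99-, 2.91-, 2.84- and 2.74-fold lower. In mast cells only Dnajc1 (3.21-fold) was called higher and 3 genes lower, among them Mir6236 (9.69-fold) and Camk1d (2.84-fold), at a depth where 222 genes could be called. With a full droplet load of free RNA taken off, 0 were lower, and without each gene's top cell, 0 were higher.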

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

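Of the tests in this part, leaving out joint cluster 2, comparing LPM within it, the doublet score limit and the full droplet load of free RNA were chosen only after the result was seen. Some gene lists had medians of opposite sign in different classes under the same contrast, each outside or on the limits of the middle 95% of its random lists, and these differences between classes were not tested. MHC class II had a median log2 ratio of -0.81 in LPM, -0.15 in B cells and -0.43 in naive CD4 T cells, against 0.63 in CD4 T cells and 0.055 in neutrophils. The signs in naive CD4 T cells and neutrophils did not hold, with 0.33 and -0.66 once the profile of nearly empty barcodes was subtracted. In CD4 T cells the B cell markers also had a median above 0 (1.75), though most of them were not called. Complement components and receptors had -0.33 in LPM and 0.15 in neutrophils. Immediate early and dissociation stress genes had 0.30 in LPM and 0.16 in B cells against -0.43 in neutrophils. Oxidative phosphorylation had 0.37 in LPM and -0.12 in naive CD4 T cells. The oxidative stress response had 0.37 in LPM and 0.12 in neutrophils against -0.24 in B cells.

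For MHC class II in LPM, the 5 members that passed the size rule had a median log2 ratio of -1.81. With a full droplet load of free RNA taken off it was -1.84, so free RNA did not account for the difference. Among LPM with a doublet score of at most 0.5 (130 of 171 naive, 366 of 413 infected) it was -2.0, so cells captured together with LPM did not account for it either, as far as the score finds them. The median score was highest in naive cluster 2 (0.343, against 0.186 to 0.239 in other naive clusters). A test of such capture by marker genes is left out here. Without joint cluster 2 in both libraries the median was -0.42, so most of the difference went with that cluster, which held 79 of 171 naive and 26 of 413 infected LPM. Its larger share in naive LPM as the whole cause requires a like level in its cells of both libraries. Among LPM of cluster 2 the median was -3.04 (-4.94 to -1.95, with cells drawn anew), so the share of the cluster as the authors drew it did not alone account for the difference. Its cells may not be of the same kind in both libraries, and the 5 genes were chosen by their call in these LPM. The cluster also had the lowest median depth in both libraries (12020 naive and 10851 infected UMIs, SPM included). In clusters 0, 1 and 3 the medians were below 0 with intervals that included it. Fewer LPM rich in class II and a lower level in each such cell are both left open, since no value here follows a cell over time.

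Barcodes outside the annotation, which the main values do not use, held signals above the 3 counts that a count of 0 allows. There were 1692 such barcodes with at least 500 UMIs in the naive and 2905 in the infected library. They held 231 and 294 Vsig4 UMIs, in 134 and 162 barcodes. They held 1669 and 218 UMIs of the haemoglobin gene Hbb-bs, in 3 and 2 barcodes, of which 1119 and 217 lay in 1 barcode. No difference between the libraries in these values was tested.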

How the results depend on the processing

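The doublet score limit, the full droplet load of free RNA, leaving out clusters, clusters of LPM without SPM, shares without monocytes and neutrophils and leaving out each gene's top cell were chosen only after the result was seen. No paired analysis was possible because each condition is 1 library and the values come from no test. Counts of genes and the range of Vsig4 among clusters were held to 1.5-fold of the main value, shares and ratios to its counting interval, and list medians to the spread of their random lists around it. By these limits 139 of the leading values stayed and 38 moved, and of the others 1098 stayed, 179 moved and 6 reversed. The type I interferon median of LPM was between 1.41 and 1.47 in the 4 alternatives run on it; the TMM shift would add 0.10, and among LPM with doublet scores of at most 0.5 it was 1.35 over members of at least 50 UMIs (1.45). The monocyte share ratio went from 6.80 to 10.1 with doublet scores of at most 0.5 and to 10.4 with marker-based classes, and the neutrophil ratio from 3.06 to 2.03 with raw barcodes. Without monocytes and neutrophils, ratios became 1.39 for LPM (0.844), 0.979 for B cells (0.592), 0.708 for T cells (0.429), 0.427 for mast cells (0.258) and 1.43 for NK cells (0.864), by construction. LPM genes higher or lower (126 and 88) became 194 and 55 under TMM, 218 and 351 with no filter, and 36 and 19 at a 2-fold bound. Genes lower became 144 at 20 UMIs and CPM 20 and 56 without cluster 2, and genes higher 75 at 200 UMIs and CPM 100 and 82 without cluster 4. Filters and bounds move these counts by construction. Subtracting the profile of barcodes with 1 to 50 UMIs gave 42 genes lower in B cells (15), 11 lower in CD4 T cells (5) and 39 higher in naive CD4 T cells (21), and interferon medians of 1.25 in B cells (1.65) and 0.72 in naive CD4 T cells (1.20). Leaving out each gene's top cell gave 4 genes lower in naive CD4 T cells (7), 21 in neutrophils (35) and 0 higher in mast cells (1). The median of gene ratios gave 19 lower in neutrophils and 5 in mast cells (3), and the full droplet load 0 lower in mast cells and an interferon median of 0.0125 in NK cells (0.31). With members of at least 50 UMIs that median was 0.91 in NK cells and 0.70 in naive CD4 T cells. LPM with Vsig4 went from 36.8% and 29.8% to 14.6% and 12.3% when thinned and to 28.7% and 24.9% at 2 UMIs, by construction. The upper against the lower part of infected LPM by Vsig4 CPM gave 1 gene lower (3), and own Leiden clusters a range of Vsig4 among infected clusters of 1.10-fold (2.42). Reversed log2 values were Retnla in LPM, -0.98 (1.24) in the subset table, which adds SPM that carry it, Ebf1 in neutrophils, 0.38 (-1.90), and Gzmc in NK cells, -0.40 (2.52), without a top cell that held most UMIs, and 3 list medians after subtracting the profile of barcodes with 1 to 50 UMIs. These were neutrophil markers in LPM, -0.29 (0.43), which the subtraction is set to bring to 0 at most, and MHC class II in naive CD4 T cells, 0.33 (-0.43), and in neutrophils, -0.66 (0.05). Except where stated, the cause was not tested. Leaving out doublets by antibody and 3 ways of scaling antibody counts between conditions were not run, because the infected matrix holds 0 antibody counts. Depth limits mast cells (222 genes could be called) and small folds in neutrophils and NK cells.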

Other observations

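The cell cycle test, the doublet score limit and the full droplet load of free RNA were chosen only after the main result was seen; what the tests on the interferon list and Arg1 were to show was written before those were run. Cell division genes of LPM went different ways. Mki67, Top2a and Stmn1 had log2 ratios of -2.82, -1.88 and -2.72, and the helicase genes Mcm3, Mcm6 and Mcm7 had 0.30, 0.13 and -0.14. Other genes of DNA replication were split, with, at under 50 CPM, Rrm2 at -1.92 (ratio 0.264, 0.166 to 0.419) and Pclaf at -2.12 (0.230, 0.171 to 0.308), and Pcna at -0.13. With LPM thinned to 7824 UMIs, Mki67 was present in 11.0% of naive (6.56 to 17.1%) and 6.31% of infected LPM (4.13 to 9.18%). Top2a was present in 18.2% (12.4 to 25.2%) and 12.6% (9.52 to 16.3%), and Mcm7 in 22.1% and 21.7%. The intervals of Mki67 and of Top2a overlapped. Cells positive for Mki67 held 3.35 UMIs on average in naive and 1.12 in infected. No cells were drawn anew for these genes, so the intervals of their ratios leave out the spread between cells. The median log2 ratio of Mcm2 to Mcm7, of which the list fixed in advance holds only Mcm3, Mcm5 and Mcm6, was 0.10. It was -1.82 for the 20 list members outside this family. These are the values that raised the question of fewer LPM in the G2 and M phases with replication kept, so they cannot support it, and it stays open.

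The type I interferon list was higher in all 6 classes compared. With a full droplet load of free RNA taken off, the lowest of the 6 medians over members of at least 50 UMIs was 0.695 log2, in naive CD4 T cells, where it rests on 10 of 36 members and was 0.695 before as well. The heavier subtraction of the profile of nearly empty barcodes lowered the median over all 36 there to 0.72, and lowered that of B cells as well. No random lists were drawn for the subtracted counts. In naive CD4 T cells this profile took off 19.7% of naive and 10.5% of infected UMIs, against 2.71% and 3.63% for the full droplet load. Free RNA so estimated may account for a part of the difference in these classes. The medians left were above 0, but without random lists it was not judged how much of the difference remains. Among cells with a doublet score of at most 0.5 the lowest of the 6 medians was 0.577. So cells captured together did not account for the whole difference, as far as the score finds them. The score exceeded 0.5 in 25.7% of naive and 9.22% of infected cells, and whether the limit means the same in both libraries is not known. With 1 library per condition, infection and any other difference between the pools or their preparation cannot be told apart.

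Arg1 was higher in infected LPM and in infected monocytes. Its UMIs per infected B cell came to 0.657% of the excess per infected LPM, so a like load of free RNA in every droplet did not account for it. Among LPM with a doublet score of at most 0.5 and no Ly6c2 or Ccr2 UMI (311 infected, 121 naive) the ratio was 5.14 (4.73 to 5.59), so monocytes captured with LPM did not either, with the same limit on the score. A different make-up of LPM was not weighed. The Arg1 ratio was 4.34, 1.22, 2.42 and 4.42 in clusters 0 to 3, and Arg1 was highest in cluster 4, which held infected cells alone. A response of LPM themselves and a different make-up of the cells labelled LPM are both left open, and with 1 library per condition each stays a hypothesis.

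Cmss1 (chromosome 16, 57301999 to 57606867) had a ratio below 1 in 9 of 9 classes, from 0.211 to 0.621. Like Cmss1, Fhit (chromosome 14, 9550092 to 11162061) and Tenm4 (chromosome 7, 96171244 to 96911093), lower in B cells, span long loci. Tppp3, lower in B cells, and Id2, lower in naive CD4 T cells, are short. Whether gene length bears on such ratios was not tested. Proliferating B cells were 3 of 1057 naive and 34 of 3025 infected cells.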
